A study of Homo sapiens with 6 samples.

How the data were processed

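ChIP-seq peak lists were analysed for LSD1 with DMSO, LSD1 with inhibitor, H3K4me2 with DMSO and H3K4me1 with DMSO, all in NCI-H526 cells. Groups were taken from the sample descriptions. The labels call the treated libraries GSK552, and the treatment protocol in the labels gives 1 µM GSK2879552, an LSD1 inhibitor, for 24 hours. The same protocol text stands with every sample and was read as applying to the GSK552 libraries only. The 6 samples included 2 inputs, which were not used here, and each group had 1 library.

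BWA, Picard and MACS2 2.0 are named in the submitters' processing notes, with genome build hg19. The versions of BWA and Picard, the input used as control, the treatment of duplicate reads and the depth are not given in the sources used here. Each list belongs to 1 library, per the labels. The files have no header, so their columns were read from the layout that MACS2 writes. The deposited score of each peak is 10 times its −log10 q, as a whole number, which was tested on the rows and held in at least 99.99% of each list. The deposited fold enrichment is a ratio of the peak over the caller's background. The deposited −log10 p and −log10 q are the authors' own values for each peak, and they were used to describe, rank or filter peaks within a list, and −log10 p with the fold also to compute the implied background, which was compared across lists relative to each list's median. The LSD1 lists have the broad-peak layout, with a smallest −log10 q of 1.00 with DMSO and 1.01 with inhibitor. The histone lists have the narrow-peak layout with several summits for an interval, with a smallest −log10 q of 2.02 for H3K4me2 and 2.01 for H3K4me1. The LSD1 lists therefore reach to weaker peaks than the histone lists, and broad and narrow intervals differ in how they are joined, which affects widths and overlaps between the kinds of list.

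The 178083 deposited rows for H3K4me2 were reduced to 81619 distinct intervals and the 175135 rows for H3K4me1 to 94689, with the highest score, fold and summit over the rows of an interval. A peak counted as overlapped when it shared at least 1 bp with a peak of the other list. Shares carry 95% Wilson intervals and differences of shares Newcombe intervals; for differences on the same H3K4me2 intervals the interval allows for the pairing of the values. All intervals cover counting error only, and neighbouring peaks are not independent. Expected overlap came from 100 draws that placed each peak at random on its chromosome and 100 draws that moved it by 50 to 500 kb, where chromosome length was the largest peak end in the lists. Since each group has 1 library, no test between conditions was run.

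The implied background of a peak is the background at which its fold, computed as pileup plus a pseudocount over background plus the same pseudocount, has its Poisson p-value. It is given relative to the list median. Stretches of raised background are runs of at least 10 consecutive peaks, over the 4 lists together, at more than 6 times the list median. Clusters of LSD1 peaks were stitched over gaps of up to 12.5 kb. The overlap search was tested on simulated data, where 50% of peaks planted to overlap were recovered at 50%. On chromosome 21 the search gave 264 overlaps and a count of all pairs 264. Random peaks had 1.04 times the expected overlap, and a simulated background ratio of 20 was recovered as 20.0. The simulated backgrounds used the same formula as the measure, so they tested the code and not whether the measure holds for these lists.

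Peaks named by position were chosen by a rule set before the data were examined: the 10 highest-scoring DMSO-only, inhibitor-only and shared LSD1 peaks, with shared peaks ordered by the mean of their ranks as a percent of each list, and the 10 highest-scoring DMSO LSD1 peaks with neither mark and with both. The text gives the leading members of each set and counts over the rest. Clusters and raised stretches were chosen after their values were seen. The gene table given for this work is on GRCh38, so it was not used with hg19 positions, no coordinates were converted, and no gene is named at a peak. For the same reason the planned shares of LSD1 peaks at promoters and the 14 planned gene lists were not analysed here. Histone marks with inhibitor were not analysed here.

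Alternatives set before the data were examined were the 50% of peaks with the highest scores in each list, equal length of the lists of a pair, a reciprocal overlap of 50%, peak centres or summits, chromosomes 1 to 22 only, list-only peaks at least 1 kb away, and moves of 50 to 500 kb in place of the whole chromosome. Chosen after the data were seen were LSD1 peaks with a −log10 q of 2 or more, leaving out the raised stretches, the 4 sizes of lists of highest-scoring peaks, equal length together with centres, runs of raised peaks of 1 list alone, equal length of the LSD1 lists against full mark lists, and the shares on H3K4me2 with and without H3K4me1 and on neither mark. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, with a fixed random seed.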

Results

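Chromatin immunoprecipitation followed by sequencing (ChIP-seq) mapped LSD1, H3K4me2 and H3K4me1 in NCI-H526, a human small cell lung cancer cell line. LSD1 (KDM1A) is an enzyme that removes methyl groups from H3K4me2 and H3K4me1. As background, H3K4me1 is common at enhancers, and H3K4me2 is found at both enhancers and promoters. The 6 samples each formed a group of 1 library. Peak lists were analysed for 4 of them, namely LSD1 with DMSO (the vehicle), LSD1 with an LSD1 inhibitor, H3K4me2 with DMSO and H3K4me1 with DMSO. The other 2 samples were inputs, which were not used here, and histone marks with inhibitor were not analysed here. There were no replicates, so every difference between lists is a difference between single libraries and carries no p-value. Wilson intervals (95%) are given for shares of peaks and cover counting error only. Positions are on hg19.

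The LSD1 list with DMSO held 45188 peaks covering 28.2 Mb, and the list with inhibitor held 49597 peaks covering 27.8 Mb. Median peak width was 471 bp with DMSO and 388 bp with inhibitor. The H3K4me2 list held 81619 intervals covering 60.1 Mb with a median width of 411 bp, and the H3K4me1 list held 94689 intervals covering 67.8 Mb with a median width of 416 bp. Read depth is not given in the sources used here. The median −log10 q, the authors' own value for each peak, was 1.95 in the LSD1 list with DMSO and 2.88 in the list with inhibitor. Of the LSD1 peaks, 48.0% with DMSO and 75.3% with inhibitor had a −log10 q of 2 or more.

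The first comparison asked how far the distribution of LSD1 with inhibitor matched that with DMSO. LSD1 peaks were found at many of the same places in both libraries. Of the 45188 DMSO peaks, 28538 (63.2%, interval 62.7 to 63.6%) were overlapped by an inhibitor peak, and of the 49597 inhibitor peaks, 28803 (58.1%, 57.6 to 58.5%) were overlapped by a DMSO peak. The overlap was closest among the strongest peaks: 998 of the 1000 highest-scoring DMSO peaks lay in the full inhibitor list, and 973 of the 1000 highest-scoring inhibitor peaks lay in the full DMSO list. The order within the lists matched less well, since 423 of the 1000 highest-scoring peaks of each list were overlapped by a peak among the 1000 highest of the other.

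Peaks moved at random within their chromosome were overlapped in 2.13% ± 0.0668 (SD, 100 draws) of cases for DMSO and 1.95% ± 0.0531 for inhibitor. Moved by only 50 to 500 kb, which keeps the local density of peaks, they were overlapped in 3.25% ± 0.0820 and 2.98% ± 0.0757 of cases. The 2 LSD1 lists shared 13.6 Mb, or 48.4% of the sequence covered with DMSO. The share of DMSO peaks found in the inhibitor list rose from 26.1% in the lowest of 10 score deciles to 96.5% in the highest, and the share of inhibitor peaks found in the DMSO list rose from 31.0% to 91.3%. With a reciprocal overlap of 50% of both peaks, the shares fell to 33.3% of DMSO peaks and 30.4% of inhibitor peaks.

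**Figure D1:**
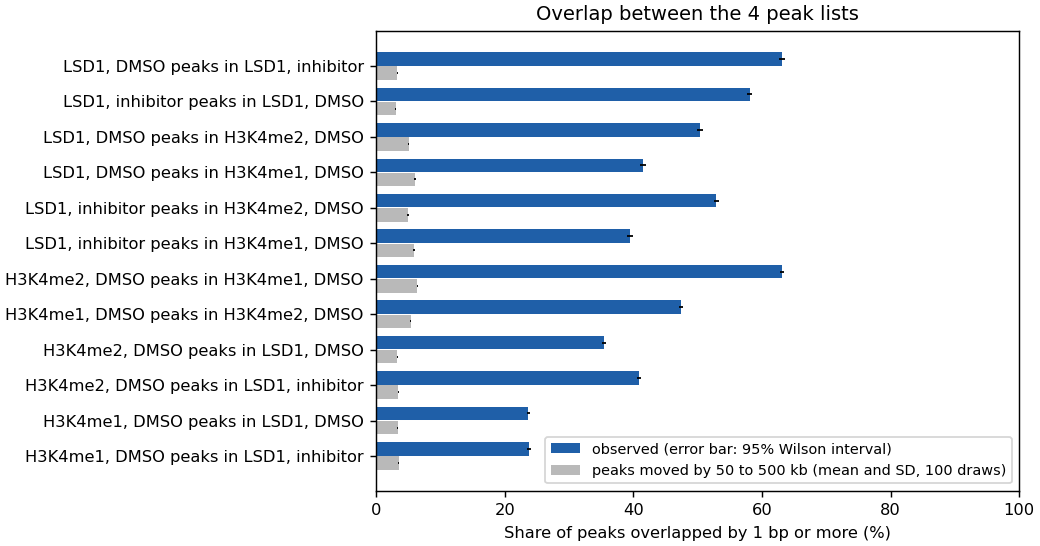
Share of the peaks of each list (percent, x axis) overlapped by 1 bp or more of another list, for 12 ordered pairs of the 4 lists. Blue bars show the observed shares with 95% Wilson intervals, grey bars the mean and SD of 100 draws in which each peak was moved by 50 to 500 kb; every observed share, from 23.7% to 63.2%, lies above the mean of its moved peaks, which is at most 6.37%.

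The peak with the highest LSD1 score with DMSO lay at chromosome 8, 61704927 to 61705831. It had a fold enrichment of 16.6 and a −log10 q of 42.9, overlapped both marks, and was also found with inhibitor, where the fold was 10.1 and the score rank 7. The shared peak at chromosome 18, 66094437 to 66095768, ranked 6 with DMSO (fold 12.4) and 9 with inhibitor (fold 12.7), and overlapped both marks. The shared peaks at chromosome 7, 12178234 to 12179668, and chromosome 14, 89761495 to 89763020, overlapped neither mark; their folds were 8.39 and 10.3 with DMSO and 13.8 and 10.98 with inhibitor. A shared peak at chromosome 1, 26774011 to 26774891, ranked 32 with DMSO and 3 with inhibitor, without either mark. Of the 10 highest-ranked shared peaks, 3 overlapped H3K4me2, 5 overlapped H3K4me1 and 5 overlapped neither. One of the 10, at chromosome 2, 15827986 to 15828529, had a fold of only 3.01 beside a −log10 q of 19.7, and the background implied by these values was 27.5 times the list median.

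Peaks found in only one LSD1 list came mostly from further down the ranking. The strongest DMSO-only peak, at chromosome 12, 6948940 to 6949607, had rank 297 (fold 7.14, −log10 q 12.0) and overlapped both marks. The next, at chromosome 5, 67382923 to 67383172, had rank 410 (fold 8.14) and overlapped H3K4me2 without H3K4me1. The strongest inhibitor-only peak, at chromosome 19, 31121154 to 31121534, had rank 147 (fold 7.89, −log10 q 18.9) and overlapped both marks, as did the next, at chromosome 9, 37904201 to 37904836, with rank 290 (fold 5.62). The inhibitor-only peaks at chromosome 13, 106849794 to 106850123, and chromosome 2, 219712410 to 219712711, had folds of 8.86 and 8.04 and overlapped neither mark. Of the 10 highest-scoring peaks of each kind, 5 DMSO-only and 6 inhibitor-only peaks overlapped neither mark, and 3 of each overlapped H3K4me2.

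Shared LSD1 peaks overlapped H3K4me2 far more often than peaks of one list alone. With DMSO, 62.8% (62.2 to 63.3%) of the 28538 shared peaks and 29.2% (28.5 to 29.9%) of the 16650 DMSO-only peaks overlapped H3K4me2. With inhibitor, the shares were 62.3% (61.7 to 62.8%) of 28803 shared and 40.0% (39.3 to 40.6%) of 20794 inhibitor-only peaks. The DMSO-only and inhibitor-only peaks differed in H3K4me2 without H3K4me1, at 11.4% (10.96 to 11.9%) and 22.3% (21.7 to 22.9%), while H3K4me1 was overlapped by 29.0% and 27.8% of them. Shared peaks were also wider, with a median of 585 bp against 333 bp for DMSO-only and 524 bp against 261 bp for inhibitor-only peaks. Their median score percentile was 62.8 against 29.96 in the DMSO list and 61.9 against 35.4 in the inhibitor list. When only the 50% of peaks with the highest scores in each list were used to call a peak shared, the gap in H3K4me2 between shared and DMSO-only peaks was 15.7 points in place of 33.6.

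The second comparison placed LSD1 relative to the marks it acts on, with DMSO. About as many LSD1 peaks lay on H3K4me2 as off it: 22773 of 45188 (50.4%, 49.9 to 50.9%). H3K4me1 was overlapped by 18774 LSD1 peaks (41.5%, 41.1 to 42.0%). Both marks were present at 14327 LSD1 peaks (31.7%), H3K4me2 alone at 8446 (18.7%), H3K4me1 alone at 4447 (9.84%) and neither at 17968 (39.8%). The peaks with both marks were the widest, with a median of 689 bp, and those with neither the narrowest, with 330 bp. Peaks moved by 50 to 500 kb overlapped H3K4me2 in 5.01% ± 0.102 and H3K4me1 in 5.99% ± 0.100 of cases (SD, 100 draws).

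Stronger LSD1 peaks were more often marked. From the lowest to the highest score decile with DMSO, overlap with H3K4me2 rose from 32.0% to 60.5%, overlap with H3K4me1 from 27.2% to 61.9%, and the share with neither mark fell from 58.1% to 28.3%. H3K4me2 without H3K4me1 was most frequent in the middle of the ranking, at 23.3% in decile 6, and lowest at the top, at 9.71% in decile 10. With a reciprocal overlap of 50%, 14.2% of DMSO LSD1 peaks matched an H3K4me2 interval and 8.23% an H3K4me1 interval. By peak centres, the H3K4me1 share was 27.4%.

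**Figure D2:**
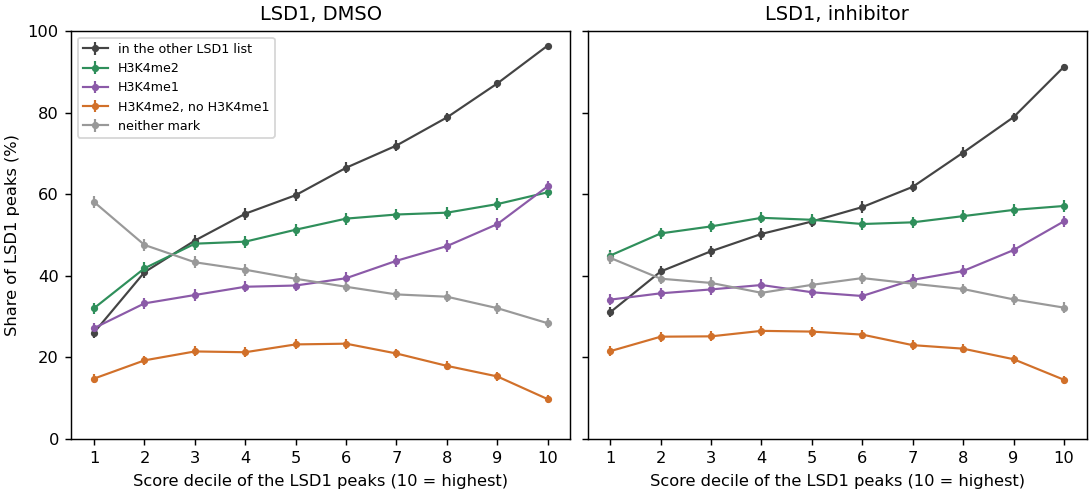
Share of LSD1 peaks (percent, y axis) with each feature in 10 deciles of the authors' score within the list (x axis), for DMSO (left) and inhibitor (right); points carry 95% Wilson intervals. Overlap with the other LSD1 list rises to 96.5% and 91.3% in the highest decile, while H3K4me2 without H3K4me1 (orange) is lowest there, at 9.71% and 14.5%.

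Among the strongest LSD1 peaks with both marks, after the chromosome 8 peak above, were chromosome 21, 43540144 to 43540917 (rank 2, fold 12.9), chromosome 13, 59983662 to 59984607 (rank 3, fold 10.9), and chromosome 2, 7341427 to 7342513 (rank 4, fold 11.5). All 3 were also found with inhibitor, where they ranked 782, 248 and 171. The strongest LSD1 peak with neither mark lay at chromosome 8, 72407515 to 72409225 (rank 5, fold 10.2, −log10 q 28.4), followed by chromosome 5, 103961754 to 103962175 (rank 9, fold 11.4). The unmarked peak at chromosome 17, 28637118 to 28640261, was 3144 bp wide and had a fold of 8.97. Each of the 10 strongest unmarked peaks was also present with inhibitor, at ranks from 3 to 9840.

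LSD1 peaks were also joined into clusters, here peaks stitched over gaps of up to 12.5 kb. Most clusters held 1 peak only, 20484 of 29237 with DMSO and 21648 of 31480 with inhibitor. Moved peaks were not stitched, so it was not tested whether the peaks cluster more than expected. The clusters below are the extremes. The cluster with the most peaks lay at chromosome 20, 55946359 to 56084668, with 45 DMSO peaks over 138 kb, of which 40 overlapped H3K4me1 and 27 overlapped H3K4me2. With inhibitor, 46 peaks formed nearly the same cluster, of which 36 were overlapped by a DMSO peak. The next 2 were at chromosome 10, 125219774 to 125319135 (26 DMSO peaks, all 26 with H3K4me1 and 10 with H3K4me2), and chromosome 11, 92198125 to 92317450 (22 peaks, 20 with H3K4me1 and 17 with H3K4me2). With inhibitor, the clusters at these 2 places held 28 and 26 peaks. The cluster at chromosome 14, 102975014 to 103060710, differed from these, with 3 of 17 DMSO peaks on H3K4me1 and 6 on H3K4me2.

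The third comparison set the 2 LSD1 lists against the same DMSO histone lists. The inhibitor list held more LSD1 peaks on H3K4me2 without H3K4me1: 11359 (22.9%, 22.5 to 23.3%) against 8446 (18.7%, 18.3 to 19.1%) with DMSO, 1.34 times as many and a difference of 4.21 points (3.70 to 4.73). The other classes differed less in number, with 14882 against 14327 peaks on both marks, 4706 against 4447 on H3K4me1 alone and 18650 against 17968 on neither. Overlap of inhibitor peaks was 52.9% (52.5 to 53.3%) with H3K4me2 and 39.5% (39.1 to 39.9%) with H3K4me1. At equal numbers of highest-scoring peaks the difference in H3K4me2 without H3K4me1 was 5.40 points at 1000 peaks (2.83 to 8.00) and 3.27 points at 20000 (2.51 to 4.03). At these sizes the inhibitor peaks overlapped H3K4me1 less often (56.1% against 66.2% at 1000 peaks, 44.9% against 50.5% at 20000) and H3K4me2 as a whole less often (56.4% against 59.6%, and 55.3% against 57.0%). The share with neither mark was then higher with inhibitor (31.6% against 26.9%, and 35.3% against 33.0%), opposite to the full lists. The 4.21 points fell to 1.97 (1.45 to 2.48) when peak centres were used, and with a reciprocal overlap of 50% the difference was −0.101 (−0.508 to 0.307), so the difference depended on how overlap was defined.

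Seen from the histone marks, more H3K4me2 intervals were overlapped by LSD1 with inhibitor, and the rise in the share was larger where H3K4me1 was absent. Of the 30087 H3K4me2 intervals without H3K4me1, 28.1% (27.6 to 28.6%) were overlapped by LSD1 with DMSO and 37.9% (37.4 to 38.5%) with inhibitor, a difference of 9.82 points (9.27 to 10.4). For the 51532 with H3K4me1, the shares were 39.7% and 42.5%, a difference of 2.81 points (2.40 to 3.22). H3K4me1 intervals without H3K4me2 were overlapped in 10.6% of cases with DMSO and 10.1% with inhibitor. The gain was larger without H3K4me1 than with it in 10 of 10 deciles of the H3K4me2 score, and was 18.6 and 9.72 points in the highest decile. By interval summits the difference was 4.47 points without H3K4me1 and −0.883 points with it, and with a reciprocal overlap of 50% it was 1.34 and −0.235 points. With LSD1 peaks of −log10 q of 2 or more, a threshold chosen after the data were seen, it was 16.0 and 10.3 points. That threshold keeps 21701 DMSO and 37356 inhibitor peaks, so the lists then differed more in length than as deposited. With both LSD1 lists at 45188 peaks, the difference was 7.32 points without H3K4me1 and 0.444 points with it.

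**Figure D3:**
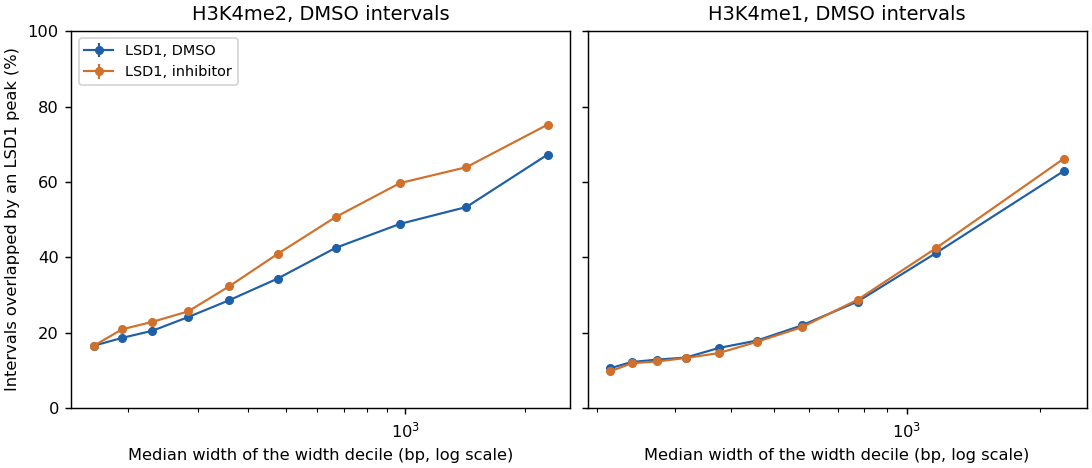
Share of H3K4me2 (left) and H3K4me1 (right) intervals overlapped by an LSD1 peak (percent, y axis) against the median width of 10 width deciles (bp, log scale, x axis), with DMSO in blue and inhibitor in orange; 95% Wilson intervals are mostly smaller than the points. In the widest H3K4me2 decile the shares are 67.3% with DMSO and 75.2% with inhibitor, and in the narrowest both are 16.5%. Wider intervals are also overlapped more often by randomly placed peaks, for which the shares are not corrected.

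The histone marks were compared with each other with DMSO. Of the H3K4me2 intervals, 63.1% (62.8 to 63.5%) overlapped H3K4me1, and of the H3K4me1 intervals, 47.4% (47.1 to 47.8%) overlapped H3K4me2. The marks shared 27.6 Mb, or 46.0% of the sequence under H3K4me2. LSD1 with DMSO overlapped 38.1% of H3K4me1 intervals that carried H3K4me2 and 10.6% of those without it. Wide intervals were overlapped by LSD1 more often, from 16.5% in the narrowest to 67.3% in the widest decile of H3K4me2 and from 10.5% to 62.9% for H3K4me1. Under the 1 bp rule a wider interval is also overlapped more often by randomly placed peaks. Median widths of these deciles ran from 164 to 2284 bp for H3K4me2 and from 214 to 2263 bp for H3K4me1. Expected overlap was not computed by width, so these values do not show a preference of LSD1 for wide intervals. With a reciprocal overlap of 50%, 15.2% of H3K4me2 intervals matched an H3K4me1 interval.

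Stretches of chromosomes 2 and 6, defined as runs of peaks above 6 times the list median over the 4 lists together, stood apart from their surroundings. The longest lay at chromosome 2, 15244767 to 16411346 (1167 kb), where the background implied by a peak's fold and p-value was a median of 21.4 times the list median for LSD1 with DMSO, 25.2 for LSD1 with inhibitor, 21.7 for H3K4me2 and 23.5 for H3K4me1. Peaks within 1 Mb on either side that were not themselves raised had medians of 0.859, 0.699, 0.660 and 0.910. Leaving out the raised ones kept 24 of 42 flanking peaks for LSD1 with DMSO, 38 of 49 for H3K4me2 and 53 of 74 for H3K4me1. These medians are therefore low in part by construction. Shorter stretches followed at chromosome 2, 16859073 to 17003489, with medians from 17.3 to 21.96, and at chromosome 6, 135464672 to 135575969, with medians from 11.0 to 13.7. The 5 stretches held 138 DMSO LSD1 peaks, 0.305% of the list, but 25 of its 1000 highest-scoring peaks, with a median fold of 2.04 against 3.61 elsewhere. With the longest run taken from 1 list alone, the medians of the other lists inside it were 21.4 to 25.4. The measure and its threshold were chosen after the data were seen.

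**Figure D4:**
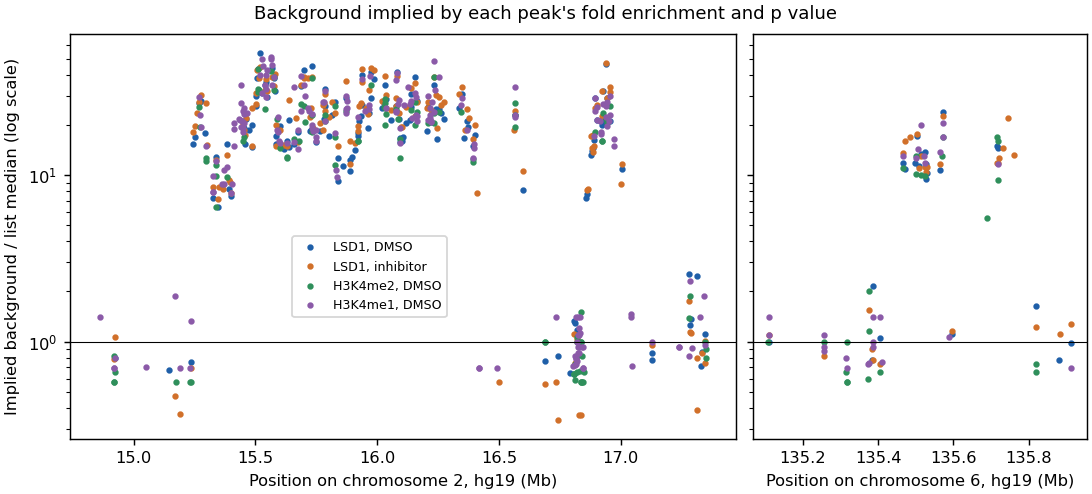
Background implied by each peak's fold enrichment and p-value, relative to the median of its list (y axis, log scale), along chromosome 2 (left) and chromosome 6 (right) in Mb on hg19; each point is a peak, coloured by list. In the longest raised stretch the 4 lists have medians from 21.4 to 25.2. Peaks within 1 Mb on either side that are not themselves raised have medians from 0.660 to 0.910, near 1, the horizontal line. The shorter raised stretches of chromosome 2 lie within that distance.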

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

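The −log10 q threshold, the removal of raised stretches, equal length with centres, and the shares below on neither mark, on H3K4me2 without or with H3K4me1, on inhibitor peaks with a mark and on LSD1 at H3K4me2 intervals were chosen after the data were seen. No paired analysis was possible because each group had 1 library and no test was run. The planned promoter shares and gene lists, with their alternatives, were not run for want of an hg19 annotation. Without the raised stretches, 14 of 14 values stayed within their counting intervals. The stretches held at most 0.305% of any list, so leaving them out could hardly have moved a value further. On chromosomes 1 to 22 only, 12 of 14 values stayed within their intervals. The others were H3K4me2 in H3K4me1 (63.6%) and H3K4me2 with inhibitor LSD1 (41.2%). Unless a sentence says otherwise, the cause of a change was not tested. Depth is unknown, so the lists cannot be compared at equal depth, and weak peaks missing from a list are not shown to be absent.

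With the 50% of peaks with the highest scores in each list, DMSO in inhibitor LSD1 was 58.9% and the reverse 54.0%; DMSO LSD1 was on H3K4me2 in 42.7% and on H3K4me1 in 39.0% of cases, and inhibitor LSD1 in 42.2% and 34.4%. H3K4me2 overlapped H3K4me1 in 47.2%, DMSO LSD1 in 28.5% and inhibitor LSD1 in 31.7% of cases. Neither mark was found at 43.1% of DMSO and 45.0% of inhibitor peaks, the opposite order to the full lists, as also under the reciprocal and −log10 q settings below. By centres the intervals of these shares overlapped (52.5 to 53.4% and 52.7 to 53.6%). The order of the H3K4me2 shares of both LSD1 lists turned under the reciprocal and −log10 q settings. Here the intervals of those shares overlapped (42.0 to 43.3% and 41.6 to 42.8%). Shared peaks exceeded DMSO-only peaks in H3K4me2 by 15.7 points and inhibitor-only peaks by 17.1. The inhibitor minus DMSO difference in peaks with H3K4me2 only was 2.84 points; at H3K4me2 intervals it was 6.05 without and 0.0623 with H3K4me1.

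With equal list length, where the longer list of each pair loses its weaker peaks, the LSD1 overlaps were 60.4% and 60.8%. With the mark list shortened to the 45188 DMSO LSD1 peaks, these were on H3K4me2 in 40.7% and H3K4me1 in 31.5% of cases and reached 46.8% of H3K4me2. With it shortened to the 49597 inhibitor peaks, the values were 45.3%, 31.3% and 53.5%, so they do not compare the LSD1 lists at equal length. H3K4me2 overlapped H3K4me1 in 60.1%. With both LSD1 lists at 45188 peaks and full mark lists, neither mark was at 36.9% of inhibitor peaks, and the differences at H3K4me2 intervals were 7.32 points without and 0.444 with H3K4me1.

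With a reciprocal overlap of 50%, which by construction excludes narrow peaks inside wide intervals, the LSD1 overlaps were 33.3% and 30.4%. DMSO LSD1 matched H3K4me2 in 14.2% and H3K4me1 in 8.23%, inhibitor LSD1 in 13.5% and 6.36%, and neither in 80.2% and 82.1% of cases. H3K4me2 matched H3K4me1 in 15.2%, DMSO LSD1 in 7.85% and inhibitor LSD1 in 8.20%. The difference in peaks with H3K4me2 only turned to −0.101 points, and at H3K4me2 intervals it was 1.34 without and −0.235 with H3K4me1.

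With peak centres or summits, the LSD1 overlaps were 47.2% and 46.5%. DMSO LSD1 was on H3K4me2 in 36.4% and H3K4me1 in 27.4%, inhibitor LSD1 in 36.8% and 25.3%, and neither in 52.9% and 53.1%. H3K4me2 was on H3K4me1 in 50.4%, DMSO LSD1 in 20.5% and inhibitor LSD1 in 21.6%. The difference in peaks with H3K4me2 only was 1.97 points, or 2.06 with equal length and centres together, and at H3K4me2 intervals it was 4.47 without and −0.883 with H3K4me1.

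With LSD1 peaks of −log10 q of 2 or more, which keeps 21701 DMSO and 37356 inhibitor peaks, DMSO in inhibitor LSD1 was 73.4% and the reverse 43.3%. DMSO LSD1 was on H3K4me2 in 56.7% and H3K4me1 in 49.4%, inhibitor LSD1 in 54.4% and 40.9%, and neither in 33.4% and 36.4%. H3K4me2 was reached by DMSO LSD1 in 20.7% and inhibitor LSD1 in 33.1%. The difference in peaks with H3K4me2 only was 5.48 points, at H3K4me2 intervals 16.0 without and 10.3 with H3K4me1, and the H3K4me2 excess of shared peaks 25.0 and 15.5 points. With list-only peaks at least 1 kb away, that excess was 38.3 and 25.7 points.

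Moving peaks by 50 to 500 kb in place of the whole chromosome lowered observed over expected overlap from 29.6 to 19.4 for DMSO in inhibitor LSD1, from 29.7 to 19.5 for the reverse, from 15.0 to 10.1 for DMSO LSD1 on H3K4me2, from 10.8 to 6.94 on H3K4me1, and from 15.9 to 9.92 for H3K4me2 on H3K4me1.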

Other observations

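By number in windows of 1 Mb, DMSO LSD1 peaks were densest at the end of chromosome 19, where the windows from 0 to 1, 1 to 2 and 3 to 4 Mb held 90, 95 and 90 peaks against a median of 14 per window. With inhibitor, against a median of 15, the window from 3 to 4 Mb of chromosome 19 came first with 85 peaks, followed by chromosome 1 from 156 to 157 Mb with 79, chromosome 19 from 0 to 1 Mb and chromosome 20 from 48 to 49 Mb with 78 each, and chromosome 2 from 15 to 16 Mb with 77, part of which lies in a raised stretch. H3K4me2 was densest on chromosome 11 from 92 to 93 Mb, with 152 intervals, where H3K4me1 had 173 and LSD1 58 with DMSO and 66 with inhibitor. Distances to summits were taken only in intervals with more than 1 summit, 30736 of 81619 for H3K4me2 and 26320 of 94689 for H3K4me1. There, LSD1 centres were about as near to the nearest summit as random positions in the same interval. The median distance with DMSO was 95 bp against 98 bp for H3K4me2 and 119 bp against 117 bp for H3K4me1. Random positions lay this close to a summit themselves, so a preference could hardly show, and intervals with 1 summit were not examined. Of the LSD1 peaks with a given class of marks with DMSO, those with H3K4me2 alone were found in the inhibitor list in 77.5% of cases (76.6 to 78.3%), those with H3K4me1 alone in 58.1% (56.6 to 59.5%). In the opposite direction the shares were 59.2% and 55.3%.

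In the weighing that follows, the predictions on narrower peaks, on strong H3K4me2 intervals and on marks under the threshold were written before their results were seen; the other tests were chosen after the result was seen.

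The inhibitor list was richer in LSD1 peaks with H3K4me2 and no H3K4me1, by 4.21 points. A longer list with inhibitor is argued against as the whole cause, since the smallest difference over 4 sizes of highest-scoring lists was 3.27 points (2.51 to 4.03), and 2.06 with equal length and centres together; but at 20000 peaks the share with neither mark was also higher with inhibitor (35.3% against 33.0%) and H3K4me2 as a whole lower (55.3% against 57.0%). Narrower peaks with inhibitor would end the difference by peak centres, which stayed at 1.97 points (1.45 to 2.48), below 4.21, so width may account for part of it; the −0.101 points under reciprocal overlap go with that explanation, although that setting itself penalises narrow peaks. A general rise over strong H3K4me2 intervals was argued against as the whole cause only. The gain was larger without H3K4me1 than with it in 10 of 10 score deciles, and under 7 of 7 alternatives, by 1.58 to 7.01 points. All 7 alternatives reuse the same LSD1 libraries. Leaving out the raised stretches kept 30086 of the 30087 intervals without H3K4me1, and chromosomes 1 to 22 kept 28850, so these settings could hardly differ. Yet in both classes the gain was larger in the highest score decile, at 18.6 points without and 9.72 with H3K4me1. In the lowest decile there was almost no gain without H3K4me1 and a slight loss with it. A larger gain over strong intervals was thus seen in the full lists and may account for part of the pattern. These deciles used LSD1 lists of unequal length and the 1 bp rule. The median interval width rose from 203 bp in the lowest to 1853 bp in the highest. With both LSD1 lists at 45188 peaks, the differences over all H3K4me2 intervals were 7.32 points without and 0.444 with H3K4me1. Deciles were not repeated at that length, so list length and interval width may enter into the larger gain. Whether the pattern reflects more LSD1 at H3K4me2 without H3K4me1 or less among the strong peaks at H3K4me1 (44.9% against 50.5% at 20000 peaks) stays open, and a difference between the libraries in depth or quality stays open, untested, because each condition had 1 library.

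The stretches of raised background were defined over the 4 lists together, so every list lies above the threshold in them by construction. The longest run, on chromosome 2, was therefore also taken from 1 list alone and measured in the others. The lowest of the 12 medians was 21.4 times the list median, so the raised background was not confined to 1 list. This measure stands for the caller's background, and the input used as control is not known. Lists with the same input would agree in it whatever the ChIP libraries did, so the values cannot decide on a fault of a single ChIP library. A raised control input shared by several lists would lower folds and remove peaks. Median folds over the 5 stretches were lower in all 4 lists, which goes with it. They were 2.04 against 3.61 elsewhere for DMSO LSD1, 2.00 against 3.92 for inhibitor LSD1, 2.64 against 6.04 for H3K4me2 and 2.34 against 5.01 for H3K4me1. Peaks per Mb, however, were at least 1.93 times (1.31 to 2.86, counting error only) those within 1 Mb on either side. This argues against a raised input as the whole cause, unless the region is rich in peaks for another reason, which was not tested. The length of 1167 kb argues against short repeats for this stretch. A candidate explanation for it is a gain in copy number in this cell line, proposed after the values were seen; the inputs that would test it directly were not used here. For the shorter stretches, of which the longest was 144 kb, short repeats cannot be told apart from copy gain by length, and the other explanations were not tested.

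LSD1 peaks with neither mark made up 39.8% of the DMSO list. Random calls are argued against as the whole cause. Of these peaks, 44.8% (44.0 to 45.5%) were found in the inhibitor list, against 2.64% ± 0.122 when they were moved by 50 to 500 kb. The share was 16.5% of 2625 peaks in the lowest score decile and 92.4% in the highest, against 39.4% and 98.1% for marked peaks. Random calls among the weaker unmarked peaks therefore stay open. An artifact common to both libraries would also recur and was not tested. Marks just outside the peak cannot be the whole cause, as 19.6% (19.0 to 20.1%) lay within 1 kb of a marked interval. Whether marks lie just under the histone thresholds cannot be told apart from absence of the mark, because the histone lists start at their threshold. Keeping only the 50% of histone intervals with the highest scores raised the unmarked share to 48.4%. Removing intervals can only keep or raise that share, so this value cannot decide the question. No biological explanation was tested.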
